A study of Mus musculus with 10 samples.

How the data were processed

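RNA of mouse embryonic stem cells of the C57BL/6 strain was sequenced in 10 libraries of 4 groups. They were 3 from wild type cells, 3 labelled Mga knockout, 2 labelled L3mbtl2 knockout and 2 labelled Pcgf6 knockout. Per the labels' protocols, total RNA was taken with Trizol and libraries were made with a NEBNext Ultra RNA kit, which does not mark strand, so reads of a gene and of its antisense partner could not be told apart. The groups and replicate numbers were taken from the labels. Whether replicates were separate clones or cultures is not given in the sources used here, so the p-values measure only the spread between these samples, which may be technical.

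The deposited values are FPKM per gene, made by the authors before deposit. Per the submitters' processing notes, Bowtie2 version 2.2.3, TopHat2 version 2.0.12 and HTSeq version 0.6.0 were used with the GRCm38 build, and how the values were scaled is not given in the sources used here. Each file listed 30460 Ensembl gene identifiers, of which 30250 were given a symbol and position by GENCODE M21 (GRCm38) and 210 were not. At 28713 genes the value was above 0 in at least 1 library, and 1747 genes were listed at 0 in all 10 libraries. The values move in steps that depend on gene length, as whole reads do. At 77.9% of the genes above 0 the values came out as whole reads, within 0.005 of a read, at the exon length of GENCODE M21, and for the other 22.1% the length was found from the values themselves. The sum of recovered reads, which is the depth of each library, lay between 19.4 and 26.7 in units of 1e6 reads. At a gene length of 2 kb, 1 read was worth 0.0187 to 0.0258 FPKM. Reads without molecular identifiers are not independent molecules, so the counting intervals and floors given here cover counting error only.

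A count model was planned. Because the deposited values are FPKM and not raw counts, the test used was limma version 3.58.1 (R 4.3.3) on log2(FPKM + 0.1), with the empirical Bayes variance prior allowed to follow mean expression. Genes with at least 0.5 FPKM in at least 2 libraries were tested, 15731 in all. All 10 libraries entered 1 fit with group as the only term, the deposited scaling was kept, and adjusted p-values are Benjamini-Hochberg values over all tested genes with a threshold of 0.05. Fold changes are on the log2(value + pseudocount) scale, which understates the change of genes near 0, and each standard error is that of limma. Each knockout was compared with wild type, and the 3 knockouts with each other. Genes with no reads in a group are given as at least so many fold higher, from a floor of 3 counts over the group, and those with 1 to 3 reads as a ratio of read rates with its exact 95% interval.

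The gene lists and the rule for naming genes were set before the data were examined. So were the other processing choices, apart from those of the main fit and those said to be added after seeing the data. The test, filter, pseudocount and scaling of the main fit replaced the planned ones once the values were seen to be FPKM. Gene lists came from general knowledge of these cells, of the complex the 3 genes belong to and of other cells a culture could hold. The 23 lists were PRC1.6 subunits, other Polycomb subunits, germ cell and meiosis, primitive and extraembryonic endoderm, trophoblast, naive and general pluripotency, primed epiblast, neuroectoderm, mesoderm and primitive streak, Hox, 2-cell-like, fibroblast (feeder cell), endothelial and blood, MYC target and ribosome biogenesis, MYC, MAX and MXD family, p53 target, S phase and E2F target, interferon response, imprinted, glycolysis and hypoxia, endoplasmic reticulum stress, sex chromosome, and mitochondrially encoded genes. Each list was tested against all other tested genes with limma's camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over 69 list tests, and again with the correlation estimated for each list. A planned self-contained test, limma's fry, was also run. It asks whether the members changed at all, not whether they changed more than other genes. List results are those of camera unless fry is named. Each list's members were counted with p adjusted over all genes and again adjusted over the list alone. Chromosomes were tested with camera at the preset correlation.

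The rule for naming genes takes the 3 targeted genes, the 8 largest rises and 8 largest falls in each comparison with wild type (5 and 5 between knockouts) among genes that passed the threshold, had a mean log2 CPM of at least 1 and had every knockout library on the same side of all wild type libraries, and up to 4 list members with the smallest p. Predicted gene models were left out of the largest changes. Fewer genes than the rule allows are named. Chromosome runs, Y-linked genes beyond the sex chromosome list and macrophage markers were chosen after their values were seen, except as stated. Members of multi-copy families (Zscan4, Xlr, Rhox, Usp17l, Tuba3, Mageb) can share reads and are uncertain as single genes.

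Overlaps between comparisons that share the wild type libraries were set beside the overlap of independent lists, and the correlation, covariance and shared sign of their fold changes beside 100 simulated draws of unchanged groups against the same controls. Unchanged groups give almost no calls, so the draws give no comparison for shared calls, and genes shared by all 3 knockouts have none beyond independent lists. Because the 3 wild type libraries cannot be split into groups of 2, part of any excess may come from the shared controls. The test was also run on simulated data with 50 genes changed at each fold size. For Mga knockout (15061 genes) it recovered 18%, 50%, 80% and 86% of genes changed by 1.5, 2, 4 and 8 fold. The shares were 24%, 48%, 70% and 84% for L3mbtl2 knockout (15052 genes) and 22%, 46%, 72% and 88% for Pcgf6 knockout (15082 genes). Both simulations gave a gene the same spread in all groups, while the libraries labelled Mga knockout varied more than the others. These shares thus do not describe the power of each comparison. The other processing choices tried were size factors by the median of ratios, upper-quartile scaling, no filter on low values, a filter of 1 CPM in 2 libraries, limma-voom on the recovered reads, a robust variance prior, a fit of only the 2 groups compared, the replicate number as a block, an estimated correlation for the lists, and leaving out each library in turn. A pseudocount of 1 or 0.01, a spread per group, and a test without the shifted chromosomes were added after seeing the data. Among tested genes with more reads, the shifted chromosomes had a median over 0.25 from wild type, on the log2 scale, in at least 1 library. They were 1, 6, 11, 12, 14, 16, 18 and Y. They were left out of every comparison, also where they were not shifted in the groups compared, so a call lost there need not come from a shift. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.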

Results

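RNA sequencing profiles of mouse embryonic stem cells, pluripotent cells of the early embryo kept in culture, were compared between wild type cells and cells labelled as knockouts of Mga, L3mbtl2 or Pcgf6. All 3 genes encode subunits of the Polycomb repressive complex PRC1.6, in which MGA binds DNA together with MAX, L3MBTL2 carries MBT domains that bind chromatin, and PCGF6 pairs with the RING1 ubiquitin ligases. The question was how the transcriptome of each knockout differs from that of wild type cells. Library depth, in 1e6 assigned reads, was 23.9, 26.7 and 26.6 in wild type and 24.8, 24.2 and 24 in the libraries labelled Mga knockout. It was 23.7 and 23 in L3mbtl2 knockout, and 23.2 and 19.4 in Pcgf6 knockout. Across genes, which are not independent replicates, pairs of libraries correlated at 0.982 to 0.983 within wild type, 0.979 within L3mbtl2 knockout and 0.978 within Pcgf6 knockout. They correlated at 0.916, 0.941 and 0.947 among the libraries labelled Mga knockout. The median standard deviation of a gene within its group, on the log2 scale, was 0.338 in Mga knockout against 0.086 in wild type, 0.064 in L3mbtl2 knockout and 0.067 in Pcgf6 knockout.

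The targeted genes were examined first. L3mbtl2 (ENSMUSG00000022394, chromosome 15, 81663889 to 81688315, GRCm38) fell from 20.2 ± 0.382 FPKM in wild type (SD, n = 3) to 3.61 ± 0.162 FPKM in L3mbtl2 knockout (SD, n = 2), a log2 fold change of -2.45 ± 0.16 (SE, adjusted p = 3.24e-05). Pcgf6 (ENSMUSG00000025050, chromosome 19, 47033617 to 47050906) fell from 28.9 ± 1.14 to 9.69 ± 0.182 FPKM in Pcgf6 knockout, a log2 fold change of -1.56 ± 0.07 (adjusted p = 2.8e-05). Mga (ENSMUSG00000033943, chromosome 2, 119897228 to 119969581) was at 18.5 ± 1.30 FPKM in wild type and at 8.03, 19.6 and 11.2 FPKM in the libraries labelled Mga knockout replicates 1, 2 and 3. These are 43.5%, 106% and 60.5% of the wild type mean, so the library labelled Mga knockout replicate 2 went against its label. The log2 fold change of Mga was -0.61 ± 0.26 and did not pass (adjusted p = 0.0987). Without the library labelled Mga knockout replicate 2 it was -0.95 (adjusted p = 0.00069), and the adjusted p ranged from 0.00069 to 0.24 over the alternatives. Values per gene sum all exons, so they cannot show a change in 1 exon, and each of the targeted transcripts still gave reads in its knockout.

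**Figure D1:**
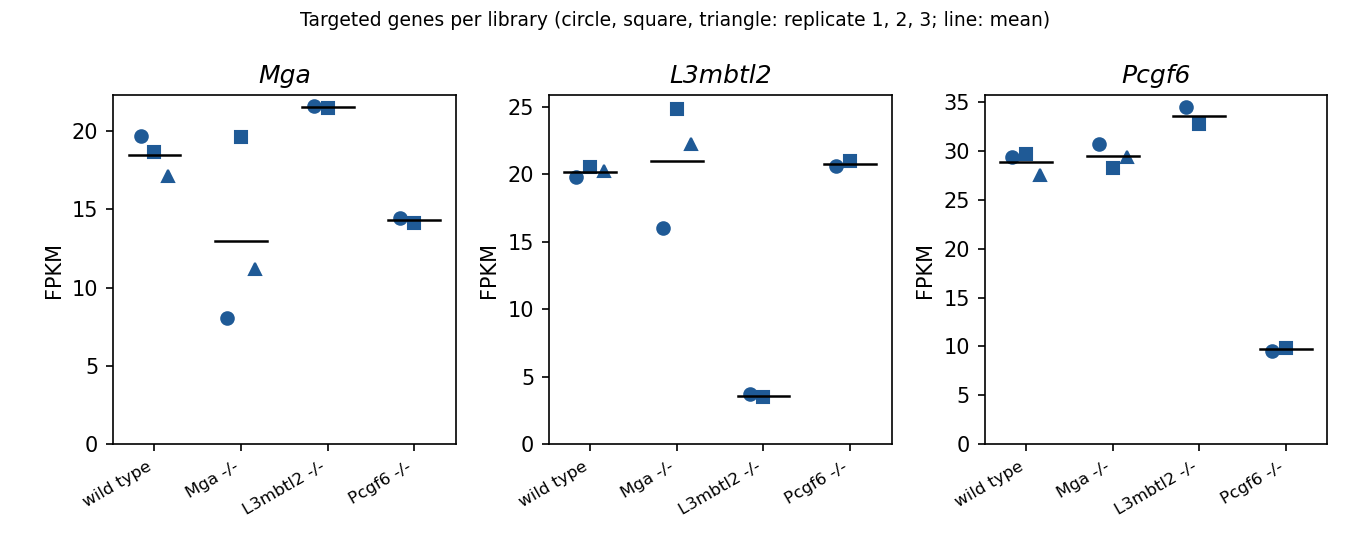
FPKM of Mga, L3mbtl2 and Pcgf6 in each library (circle, square and triangle are replicates 1, 2 and 3, and the line is the group mean). L3mbtl2 and Pcgf6 lie below every other library in their own knockouts, while the library labelled Mga knockout replicate 2 holds Mga at 19.6 FPKM, within the range of wild type.

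Germ cell and meiosis genes rose in the libraries labelled Mga knockout. Dazl, an RNA-binding protein of germ cells, rose from 1.1 ± 0.299 to 237 ± 89.3 FPKM (SD, n = 3 and 3), a log2 fold change of 7.58 ± 0.29 (SE, adjusted p = 1.25e-06). Tex12, a component of the synaptonemal complex that joins paired chromosomes in meiosis, rose from 0.357 ± 0.244 to 143 ± 7.85 FPKM (8.44 ± 0.35, adjusted p = 1.86e-06). Ddx4, a germ cell RNA helicase, rose from 9.72 ± 0.491 to 173 ± 6.74 FPKM (4.14 ± 0.07, adjusted p = 6.95e-09). Slc25a31, an ADP/ATP carrier of the testis, rose from 0.551 ± 0.106 to 86.6 ± 12.2 FPKM (7.06 ± 0.17, adjusted p = 8.82e-08). The rises of Tex101, Tdrd9, Fkbp6, Rhox13 and Syce1 were 8.44, 7.45, 7.04, 7.04 and 4.31 on the log2 scale. Of the 57 germ cell genes tested, 45 rose and 1 fell over all genes tested (48 and 1 adjusted over the list alone), and the list median was 3.19 (adjusted p = 9.66e-18). That list call was lost at adjusted p = 0.649 with an estimated correlation. By library, the median of the list was 3.56 and 4.13 in replicates 1 and 3 and 2.21 in the library labelled Mga knockout replicate 2, which held wild type levels of Mga.

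Genes of the 2-cell-like state, a rare state of embryonic stem cells that resembles the embryo after its first division, rose as well. Zscan4f and Zscan4d, which had no reads in wild type, were at least 285-fold and at least 149-fold higher, and Tmem92 was at least 56.8-fold higher. Of 15 genes tested, 12 rose and none fell (13 adjusted over the list alone), with a median of 3.10, or 3.94 with the 9 genes without wild type reads at their bound (adjusted p = 0.000124). With an estimated correlation the adjusted p = 0.649. Hox genes, which pattern the body axis, followed the same direction, with 10 of 20 higher and none lower (12 adjusted over the list alone) and a median of 1.41 (adjusted p = 0.000665, and adjusted p = 0.649 with an estimated correlation). Hoxc13 rose by 2.68 ± 0.32 (adjusted p = 0.00048) and Hoxa10 by 2.16 ± 0.33 (adjusted p = 0.00155), both from under 0.5 FPKM.

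Among pluripotency genes, Nanog rose from 143 ± 2.31 to 442 ± 23.2 FPKM (SD, n = 3 and 3), a log2 fold change of 1.62 ± 0.06 (adjusted p = 1.14e-06). Tbx3 rose from 2.99 ± 0.189 to 43.5 ± 14.1 FPKM (3.77 ± 0.19, adjusted p = 5.36e-06) and Klf4 by 2.90 ± 0.17 (adjusted p = 1.24e-05). Of 32 members 16 rose and 5 fell (17 and 5 adjusted over the list alone), and the list as a whole did not pass (median 0.38, adjusted p = 0.0526). It did pass without the library labelled Mga knockout replicate 3 (adjusted p = 0.00628), without wild type replicate 2 (adjusted p = 0.0488) and without wild type replicate 3 (adjusted p = 0.043), in a range of 0.00628 to 0.311 over the alternatives. In the primitive and extraembryonic endoderm list, 11 of 36 rose and 1 fell (10 and 1 adjusted over the list alone). Gata4, a transcription factor of that lineage, rose by 3.28 ± 0.22 (adjusted p = 3.14e-05), and Nid2, a basement membrane protein, by 2.35 ± 0.23 (adjusted p = 0.000193). The list median was 0.48 (adjusted p = 0.0948). It passed under median-of-ratios size factors (adjusted p = 0.0448) and without the library labelled Mga knockout replicate 2 (adjusted p = 0.0139), in a range of 0.0139 to 0.522. Fibroblast genes had a median of 1.34 in the library labelled Mga knockout replicate 1 and of -0.28 and -0.10 in the others. The endoderm list had medians of 0.90, 0.13 and 0.31 in the same libraries. Over all 3 libraries, 2 of 23 fibroblast genes rose (Timp3 and Lox, an enzyme that links collagen, by 1.94 ± 0.29) and 1 fell, the same counts adjusted over the list alone (median 0.21, adjusted p = 0.705).

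Epithelial keratins of the trophoblast list were lower. Krt19 fell from 30 ± 1.64 to 2.87 ± 1 FPKM (-3.40 ± 0.23, adjusted p = 3.05e-05) and Krt8 from 175 ± 2.53 to 39.5 ± 27.4 FPKM (-2.36 ± 0.38, adjusted p = 0.00193), while Tfap2a rose by 2.01 ± 0.19 (adjusted p = 0.000176). In all, 4 of 24 trophoblast genes rose and 8 fell (5 and 9 adjusted over the list alone), with a median of -0.56 (adjusted p = 0.0948). By library the median was -0.15, -1.07 and -0.20, so it leaned on the library labelled Mga knockout replicate 2, which held wild type levels of Mga. Without that library the adjusted p was 0.541, and without replicate 3 the list passed (adjusted p = 0.0456, range 0.0456 to 0.541). Imprinted genes, which are expressed from 1 parental copy, fell with a median of -0.36 (adjusted p = 0.0345, and adjusted p = 0.649 with an estimated correlation), 2 rising and 7 falling of 24 (4 and 7 adjusted over the list alone). Phlda2 fell with a log2 fold change of -3.40 (adjusted p = 8.06e-05) and Peg3 with one of -3.43 (adjusted p = 0.00021). The imprinted list did not pass under median-of-ratios size factors (adjusted p = 0.0616) or without the libraries labelled Mga knockout replicate 1 (0.0718) or 2 (0.155), in a range of 0.00964 to 0.155.

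Genes of ribosome production and other MYC targets were lower by small amounts. None of 32 rose and 11 fell, with the same counts adjusted over the list alone (median -0.14, adjusted p = 0.000903, and adjusted p = 0.649 with an estimated correlation). The 3 with the smallest p, Npm1 (-0.82), Mybbp1a (-0.86) and Pes1 (-0.51), lie on chromosome 11, whose genes had a median of -0.36 relative to the rest. At the preset correlation, the list still passed without the shifted chromosomes. Of the p53 targets 14 of 24 rose and 1 fell (15 and 1 adjusted over the list alone, median 0.38, adjusted p = 0.00766, and adjusted p = 0.649 with an estimated correlation). Trp53inp1 rose by 0.78 ± 0.10 and Pmaip1, which promotes cell death, fell by 1.03 on the log2 scale. Mitochondrially encoded genes rose at 8 of 12 members, none falling, with the same counts adjusted over the list alone (median 0.86, adjusted p = 0.0054, and adjusted p = 0.649 with an estimated correlation), mt-Cytb by 1.05 ± 0.16. Mitochondrial genes held 4.10%, 3.09% and 3.70% of reads in the libraries labelled Mga knockout and 2.84% to 3.09% in wild type. Glycolysis and hypoxia genes rose at 5 of 24 members and fell at 3, with the same counts adjusted over the list alone (median -0.15, adjusted p = 0.753). The E2f6 gene, which encodes another PRC1.6 subunit, rose from 11.2 ± 0.171 to 34.4 ± 4.81 FPKM (1.61 ± 0.10, adjusted p = 2.09e-05).

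The largest falls were in macrophage and Y-linked genes and in Klhl13, an adaptor of a ubiquitin ligase, which went from 306 ± 10.5 to 9.24 ± 0.839 FPKM (-5.04 ± 0.08, adjusted p = 6.95e-09). Lyz2, the lysozyme of macrophages, fell by 6.77 on the log2 scale (SE 1.05, adjusted p = 0.00169), Ccl6 by 5.47 (adjusted p = 7.59e-05) and Clec4n by 4.68 (adjusted p = 0.000418). Lyz2 was at 94.4 ± 1.65 FPKM in wild type and at 2.55 ± 4.08 FPKM in the libraries labelled Mga knockout, with 7.26 FPKM in replicate 1. Pf4 had 1 read in the group, at a rate 164-fold lower than wild type (95% counting interval 29.0 to 6500). Eif2s3y on chromosome Y fell by 5.46 (adjusted p = 6.68e-05). In the sex chromosome list 4 of 6 genes fell and 1 rose, with the same counts adjusted over the list alone (median -3.38, adjusted p = 0.0127, and adjusted p = 0.649 with an estimated correlation). Without the shifted chromosomes the list held only Xist and Tsix, which share reads of opposite strands (adjusted p = 0.549, range 0.00282 to 0.549).

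In the test over all genes, 6210 of 15731 differed between the libraries labelled Mga knockout and wild type, 3588 higher and 2622 lower, of which 1503 and 982 changed at least 2-fold. The balance turned to 2898 higher and 3130 lower under median-of-ratios size factors (48.1% higher against 57.8%), and was 3029 and 3008 under upper-quartile scaling. The count was 3709 with a spread per group, 4054 with only these 6 libraries in the fit, and 4067 without genes of the shifted chromosomes. Without the library labelled Mga knockout replicate 2, whose Mga level was that of wild type, 8647 genes passed. Leaving it out also raised the count of Pcgf6 knockout against wild type, a comparison that does not hold it. All groups share 1 spread, which was largest in Mga knockout (median standard deviation 0.338 against 0.086 in wild type). The added calls thus need not come from the Mga level of that library.

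In L3mbtl2 knockout cells, germ cell genes rose and keratins of the trophoblast list fell. Tex101, a surface protein of germ cells, rose from 0.644 ± 0.159 (SD, n = 3) to 324 ± 7.36 FPKM (SD, n = 2), a log2 fold change of 8.79 ± 0.87 (SE, adjusted p = 0.000224). Mael, which acts in the piRNA pathway that silences transposons, rose from 3.56 ± 0.351 to 166 ± 1.94 FPKM (5.51 ± 0.24, adjusted p = 5.16e-06). Dazl rose by 5.95 ± 0.33 (adjusted p = 1.28e-05), Ddx4 by 3.99 ± 0.07 (adjusted p = 2.5e-08), Stk31 by 4.47 ± 0.21 (adjusted p = 6.58e-06) and Zcwpw1, a reader of meiotic recombination sites, by 4.08 ± 0.13 (adjusted p = 9.48e-07). Taf7l, Rhox13 and Dmrtc2 rose by 7.05, 8.10 and 6.27. Lypd4 had 1 read in wild type and a rate 3930-fold higher (95% counting interval 704 to 155000), and its call did not hold with limma-voom (adjusted p = 0.0856, range 8.35e-08 to 0.0856). Of 57 germ cell genes 32 rose and 3 fell (34 and 4 adjusted over the list alone), with a median of 1.92 (adjusted p = 6.14e-07, and adjusted p = 0.649 with an estimated correlation).

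The largest falls were Klhl13, from 306 ± 10.5 to 3.89 ± 0.180 FPKM (-6.26 ± 0.09, adjusted p = 4.39e-09), and Nccrp1 (-6.14 ± 0.37, adjusted p = 2.05e-05). Keratins followed, with Krt8 falling from 175 ± 2.53 to 7.04 ± 0.469 FPKM (-4.61 ± 0.42, adjusted p = 0.00016), Krt19 by 4.91 (adjusted p = 1.13e-05) and Krt18 by 3.90 (adjusted p = 0.0015). Cldn4, a tight junction protein, fell by 4.37 (adjusted p = 1.36e-05), and Ap1m2, which sorts membrane proteins in epithelia, by 4.30 (adjusted p = 7.91e-05). In the trophoblast list 1 of 24 rose and 13 fell (2 and 16 adjusted over the list alone), with a median of -1.38 (adjusted p = 0.00016, and adjusted p = 0.649 with an estimated correlation).

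Pluripotency genes rose as a list in L3mbtl2 knockout, 19 of 32 rising and 4 falling (20 and 4 adjusted over the list alone), with a median of 0.56 (adjusted p = 0.000665, and adjusted p = 0.649 with an estimated correlation). Nanog rose from 143 ± 2.31 to 600 ± 0.996 FPKM (2.06 ± 0.07, adjusted p = 9.48e-07), Tbx3 by 3.76 ± 0.21 (adjusted p = 1.33e-05) and Klf5 by 2.29 ± 0.12 (adjusted p = 1.13e-05), while Dppa4, on chromosome 16, fell by 1.12 (adjusted p = 4.22e-05). Imprinted genes fell at 8 of 24 members and rose at 2 (9 and 2 adjusted over the list alone), with a median of -0.83 (adjusted p = 0.000665, and adjusted p = 0.352 with an estimated correlation). Sfmbt2 fell by 3.53 (adjusted p = 6.58e-06), and Igf2, a fetal growth factor, by 3.19 (adjusted p = 0.000452). Glycolysis and hypoxia genes fell at 15 of 24 members and rose at 5, with the same counts adjusted over the list alone (median -0.72, adjusted p = 0.000545, and adjusted p = 0.649 with an estimated correlation). Slc2a1, a glucose transporter, fell by 0.71 (adjusted p = 0.000344), Aldoa by 0.73 (adjusted p = 0.000846) and Egln3, an oxygen sensor, by 2.81 (adjusted p = 6.83e-05). Mitochondrially encoded genes rose at 9 of 12 members, none falling (10 adjusted over the list alone), with a median of 0.84 (adjusted p = 0.00766, and adjusted p = 0.649 with an estimated correlation), while the mitochondrial share of reads was 3.68% and 3.50%.

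Other lists did not pass in L3mbtl2 knockout. Primitive and extraembryonic endoderm genes rose at 12 of 36 members and fell at 3, with the same counts adjusted over the list alone (median 0.59, adjusted p = 0.403), Gata4 by 2.09 ± 0.25 (adjusted p = 0.00051). The only 2-cell-like gene of 15 that rose was Gm5662 (also adjusted over the list alone, list median 0.48, or 0.55 with genes without wild type reads at their bound, adjusted p = 0.592). It had 3 reads in wild type and a rate 28.1-fold higher (95% counting interval 9.08 to 141). Its call was lost without L3mbtl2 knockout replicate 1 (adjusted p = 0.0951) or 2 (0.0534), in a range of 1.63e-05 to 0.137. Hoxb9 was the only Hox gene of 20 to rise, by 1.27 ± 0.36 (adjusted p = 0.0219, none adjusted over the list alone, list adjusted p = 0.425). Without wild type replicate 3 (0.0708) or L3mbtl2 knockout replicate 1 (0.0991) or 2 (0.11) that call was lost, in a range of 0.000174 to 0.11. The p53 targets rose at 10 of 24 and fell at 2 (11 and 2 adjusted over the list alone, median 0.34, adjusted p = 0.152). MYC targets rose at 5 of 32 and fell at 9, with the same counts adjusted over the list alone (median -0.11, adjusted p = 0.152). Ncl and Wdr12, which rose by 0.68 and 1.01, lie on chromosome 1, whose genes had a median 0.65 above the rest. In the sex chromosome list Xist, Tsix and Uty rose and none of 6 fell (4 higher adjusted over the list alone, median 1.07, adjusted p = 0.254). The calls of all 3 were lost without L3mbtl2 knockout replicate 1 or 2 (adjusted p from 0.0565 to 0.194). Uty was lost also without any 1 wild type library, under median-of-ratios size factors (0.0511), with no filter on low values (0.0629) and at a pseudocount of 0.01 (0.294, range 0.000213 to 0.294). Tsix was lost also without wild type replicate 2 (0.0627) and at a pseudocount of 1 (0.072, range 0.000931 to 0.17). Fibroblast genes fell at Cnn1 and Fstl1 of 23 (none adjusted over the list alone) with a median of 0.14 and a mean of -0.02 (test downward, adjusted p = 0.645). Both calls were lost without either L3mbtl2 knockout library (0.0712 to 0.116), that of Fstl1 also without any 1 wild type library (0.0628 to 0.0658).

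Over all genes, 6297 of 15731 differed between L3mbtl2 knockout and wild type, 3675 higher and 2622 lower, of which 1656 and 1213 changed at least 2-fold. Under median-of-ratios size factors, which moved the median of all genes from 0.131 to 0.016, 2950 were higher and 3246 lower (47.6% higher against 58.4%). The count was 2829 and 3082 without L3mbtl2 knockout replicates 1 and 2, 4045 without the shifted chromosomes, 11110 with a spread per group and 10525 with only these 5 libraries in the fit.

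In Pcgf6 knockout cells, 2-cell-like and germ cell genes rose. Zscan4f, without reads in wild type, was at least 374-fold higher, and Xlr5a was 459-fold higher by its read rate (95% counting interval 126 to 3800, 2 reads in wild type). Rhox13 rose from 0.308 ± 0.0741 (SD, n = 3) to 44.6 ± 1.22 FPKM (SD, n = 2), a log2 fold change of 6.79 ± 0.81 (SE, adjusted p = 0.00252), though not with limma-voom (adjusted p = 0.109, range 1.46e-07 to 0.109). Mageb4 rose by 5.11 ± 0.45 (adjusted p = 0.0007). Of the 15 2-cell-like genes 13 rose and none fell (15 adjusted over the list alone), with a median of 3.77, or 4.70 with the 9 genes without wild type reads at their bound (adjusted p = 1.62e-11, and adjusted p = 0.649 with an estimated correlation). Syce1, a protein of the synaptonemal complex, rose from 3.76 ± 0.0873 to 45.6 ± 0.398 FPKM (3.57 ± 0.11, adjusted p = 2.61e-06). Ddx4, Mael and Mov10l1, the last 2 of the piRNA pathway, rose by 2.15, 3.67 and 3.80. Of 57 germ cell genes 22 rose and none fell (30 adjusted over the list alone), with a median of 1.26 (adjusted p = 3.41e-12, and adjusted p = 0.649 with an estimated correlation).

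Pluripotency genes rose at 11 of 32 members and fell at 4 (13 and 4 adjusted over the list alone), with a median of 0.38 (adjusted p = 0.00101, and adjusted p = 0.649 with an estimated correlation). Tbx3 rose from 2.99 ± 0.189 to 21.3 ± 1.05 FPKM (2.79 ± 0.21, adjusted p = 0.000282) and Klf4 by 2.01 ± 0.19 (adjusted p = 0.000803). Lefty1, a Nodal inhibitor, fell from 360 ± 27.4 to 54.0 ± 0.522 FPKM (-2.73 ± 0.28, adjusted p = 0.00121). Endoderm genes rose at 9 of 36 members, none falling (11 adjusted over the list alone), with a median of 0.42 (adjusted p = 0.0021, and adjusted p = 0.649 with an estimated correlation), Cubn, a receptor of the visceral endoderm, by 3.29 ± 0.29 and Gata4 by 2.70 ± 0.25. That list did not pass without the shifted chromosomes (adjusted p = 0.157, range 0.00101 to 0.157). The chromosomes left out there include some not shifted in Pcgf6 knockout. Chromosome 14, which holds Gata4, lay at 0.024 and 0.028 in the Pcgf6 knockout libraries, so the loss need not come from a shift. Bmp4, a signalling protein of the early embryo, rose by 2.47 ± 0.12 (adjusted p = 2.8e-05) and Cdx1 by 2.84 ± 0.22 (adjusted p = 0.000368). The trophoblast list fell at 5 of 24 members, none rising (8 adjusted over the list alone), with a median of -0.67 (adjusted p = 0.00108, and adjusted p = 0.649 with an estimated correlation). Krt8 fell by 2.98 (adjusted p = 0.005) and Krt19 by 1.94 (adjusted p = 0.00385). Both calls were lost without Pcgf6 knockout replicate 1 or 2, which leaves 1 library in the group. The log2 fold changes held, at -3.04 to -2.93 for Krt8 and -1.99 to -1.81 for Krt19 over the alternatives.

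Y-linked genes fell in Pcgf6 knockout, among them Eif2s3y from 8.87 ± 0.614 to 0.480 ± 0.00566 FPKM (-3.95 ± 0.48, adjusted p = 0.00261), Kdm5d by 3.05 (adjusted p = 0.0011) and Uba1y by 2.77 (adjusted p = 0.000473). The call of Eif2s3y was lost at a pseudocount of 0.01 (adjusted p = 0.0561, range 2.7e-07 to 0.0561). In the sex chromosome list 4 of 6 fell and none rose, with the same counts adjusted over the list alone (median -2.67, adjusted p = 0.000545, and adjusted p = 0.649 with an estimated correlation). Without the shifted chromosomes only Xist and Tsix were left in it (adjusted p = 0.976, range 0.000267 to 0.976). Glycolysis and hypoxia genes rose at Hk2, Pfkp and Gpi1 of 24, none falling, with the same count adjusted over the list alone (median 0.19, adjusted p = 0.0237, and adjusted p = 0.784 with an estimated correlation). The list did not pass under median-of-ratios size factors (0.0599), without the shifted chromosomes (0.159) or without wild type replicate 1 (0.051), in a range of 0.00537 to 0.159. Hk2, a hexokinase, rose by 0.71 ± 0.10 (adjusted p = 0.00548), with 0.0726 and 0.0653 without Pcgf6 knockout replicates 1 and 2 (range 1.49e-06 to 0.0726). The calls of Pfkp and Gpi1 were lost without either Pcgf6 knockout library as well (0.0814 to 0.217), and that of Gpi1 without any 1 wild type or L3mbtl2 knockout library (0.0703 to 0.116). Gpi1 did not pass under median-of-ratios size factors (0.114) or upper-quartile scaling (0.0637) either (range 4.3e-05 to 0.217). Mitochondrially encoded genes rose at mt-Nd5 and mt-Nd6 of 12, none falling (4 adjusted over the list alone, median 0.43, adjusted p = 0.0174, and adjusted p = 0.649 with an estimated correlation). The list did not pass without wild type replicate 3 (0.0588, range 0.00486 to 0.0588). Both single calls were lost without any 1 wild type library or either Pcgf6 knockout library, and that of mt-Nd6 without either L3mbtl2 knockout library too (adjusted p from 0.0626 to 0.24) and with no filter on low values (0.0633). Mitochondrial genes held 3.61% and 3.47% of reads. Fibroblast genes had a median of -0.59 (adjusted p = 0.0034, and adjusted p = 0.784 with an estimated correlation), with Cnn1 the only one of 23 to fall and none to rise, also adjusted over the list alone. Cnn1 was lost without any 1 wild type library or either Pcgf6 knockout library (0.0638 to 0.14). Imprinted genes rose at 3 of 24 and fell at 2 (5 and 3 adjusted over the list alone, median -0.05, adjusted p = 0.91), Sfmbt2 falling by 2.14 (adjusted p = 0.000314).

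Of 20 Hox genes none passed with limma in Pcgf6 knockout, also adjusted over the list alone (list adjusted p = 0.465). One p53 target of 24 rose (Gtse1) and 1 fell (Aen), against 0 and 1 adjusted over the list alone, with a median of 0.00, a mean of -0.08 and a downward test (adjusted p = 0.812). Among 32 MYC targets 1 rose (Nop16) and 3 fell (Npm1, Eif4a1 and Mybbp1a, all on chromosome 11, whose genes had a median of -0.37 relative to the rest), against 3 and 4 adjusted over the list alone (median 0.09, adjusted p = 0.812). These 6 calls were each lost without either Pcgf6 knockout library, that of Npm1 also without wild type replicate 1 or 2, and the others without any 1 wild type library. Those of Gtse1, Aen, Nop16 and Mybbp1a were lost without either L3mbtl2 knockout library too (adjusted p from 0.0506 to 0.27 over all of these). With no filter on low values Gtse1, Nop16 and Mybbp1a did not pass (0.0741, 0.0617 and 0.0528), and Gtse1 was lost also under median-of-ratios size factors (0.0595), with limma-voom (0.0526) and without the shifted chromosomes (0.0559, range 7.23e-05 to 0.27).

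Over all genes, 1584 of 15731 differed between Pcgf6 knockout and wild type, 857 higher and 727 lower, of which 433 and 195 changed at least 2-fold. The balance turned to 756 higher and 896 lower under median-of-ratios size factors (45.8% higher against 54.1%), and was 907 and 735 under upper-quartile scaling. Leaving out Pcgf6 knockout replicate 1 or 2 left 182 or 154, wild type replicate 1, 2 or 3 left 582, 515 or 621, and L3mbtl2 knockout replicate 1 or 2 left 924 or 925, while 3586 and 3975 passed without the libraries labelled Mga knockout replicates 1 and 2. The count was 7503 with a spread per group and 7096 with only these 5 libraries in the fit. It was 782 without the shifted chromosomes, of which 538 were higher (68.8% against 54.1%). Of the chromosomes left out there, 1, 6, 12, 14 and 18 were not shifted by over 0.25 in Pcgf6 knockout.

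**Figure D2:**
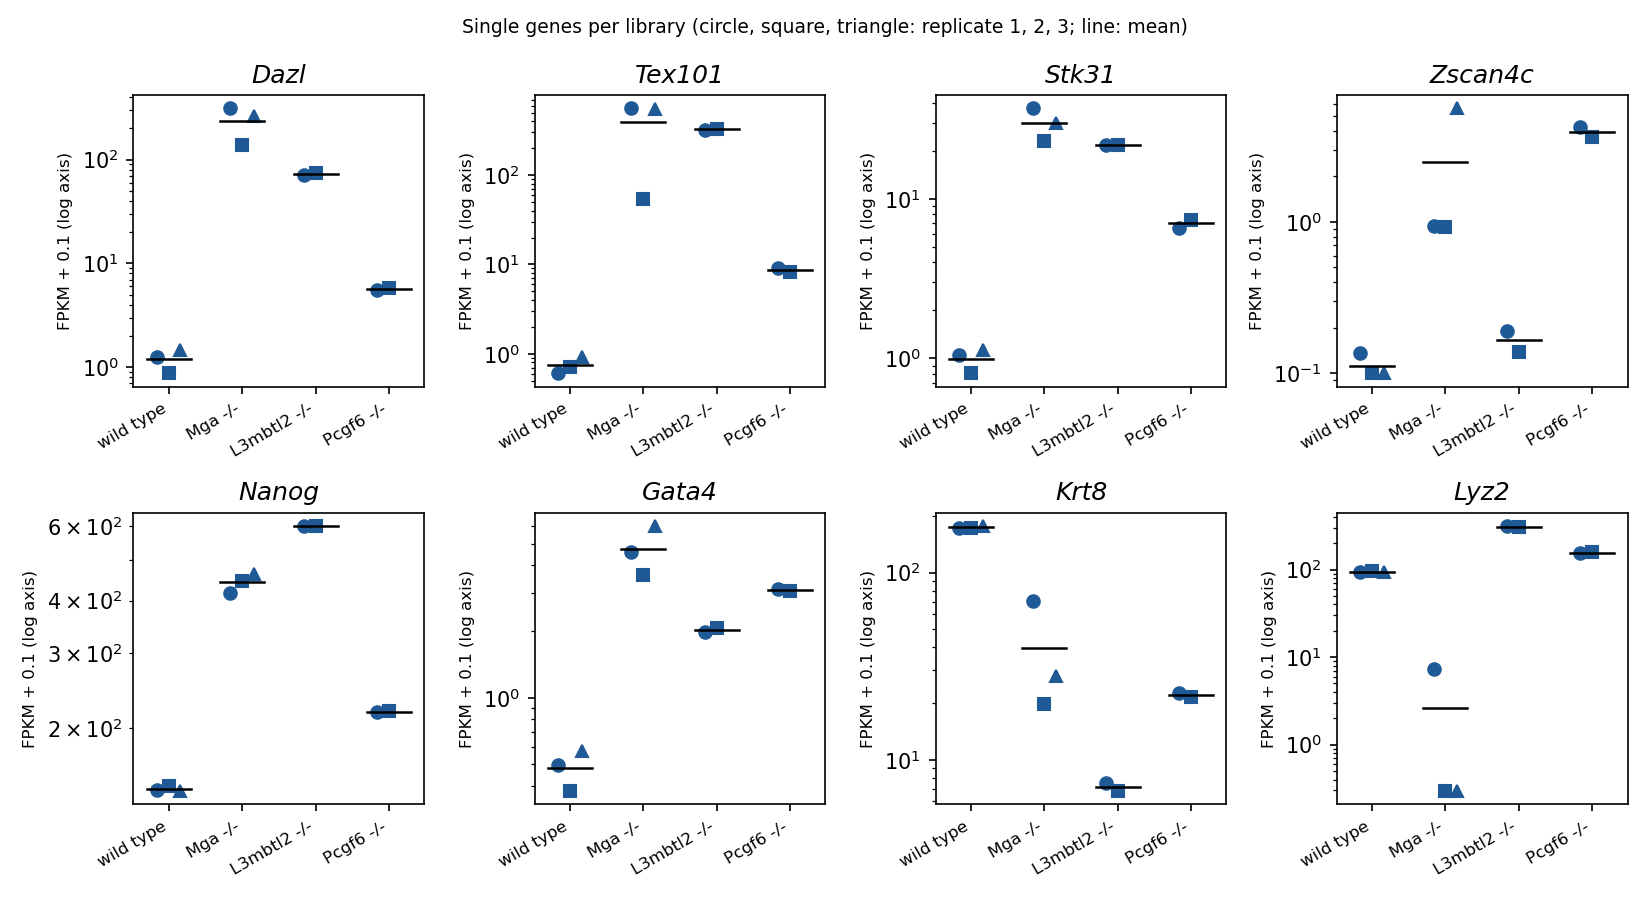
FPKM + 0.1 on a log axis in each library for Dazl, Tex101, Stk31, Zscan4c, Nanog, Gata4, Krt8 and Lyz2 (circle, square and triangle are replicates 1, 2 and 3, and the line is the group mean). Dazl is above wild type in every knockout library, Krt8 is below it, and Lyz2 is lower in the libraries labelled Mga knockout (7.26 FPKM in replicate 1). In L3mbtl2 and Pcgf6 knockout Lyz2 is higher than wild type by 1.71 and 0.72 on the log2 scale, which did not pass with limma (adjusted p = 0.274 and 0.76). Its values do not overlap, at 305 and 315 FPKM and at 153 and 159 FPKM against 93.3 to 96.3 FPKM in wild type. All groups share 1 spread in the fit, so these p-values also carry the spread of the libraries labelled Mga knockout.

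The other lists did not pass camera in any comparison with wild type. Some did pass fry, whose adjusted p is given for Mga, L3mbtl2 and Pcgf6 knockout in turn. It was 0.00107, 5.97e-06 and 0.00491 for primed epiblast, 0.00193, 0.0132 and 0.211 for PRC1.6 subunits, and 0.00193, 0.211 and 0.00195 for mesoderm genes. For the MYC, MAX and MXD family it was 0.00814, 0.0104 and 0.031, and for other Polycomb subunits 0.13, 0.0213 and 0.967. Neuroectoderm genes were at 0.0238, 0.169 and 0.34 with fry, and endothelial and blood genes at 0.105, 0.045 and 0.469. Interferon genes were at 0.128, 0.0306 and 0.289, and endoplasmic reticulum stress genes at 0.177, 0.0168 and 0.586. For S phase genes it was 0.978, 0.721 and 0.236. The adjusted p-values below are those of camera. PRC1.6 subunits rose and fell at 3 and 1 of 15 members in the libraries labelled Mga knockout, at 6 and 3 in L3mbtl2 knockout and at 3 and 1 in Pcgf6 knockout, the targeted genes included (adjusted p of 0.645, 0.582 and 0.789). E2f6 was higher in all 3, by 1.61, 1.33 and 0.82, the last lost without Pcgf6 knockout replicate 2 (adjusted p = 0.0728, range 4.38e-06 to 0.0728). Other Polycomb subunits rose and fell at 9 and 9, 8 and 5, and 1 and 2 of 27 members (0.753, 0.812 and 0.812), with Bmi1 rising by 1.84 ± 0.20 in the libraries labelled Mga knockout and 1.56 ± 0.23 in L3mbtl2 knockout, and Phf19 falling by 2.48 in L3mbtl2 knockout. In the libraries labelled Mga knockout that list had a median of -0.01, a mean of 0.07 and a downward test, and in Pcgf6 knockout 0.04, -0.03 and a downward test. Primed epiblast genes rose and fell at 6 and 6, 7 and 7, and 5 and 2 of 18 (0.812, 0.448 and 0.865). Otx2, a transcription factor of the primed epiblast, rose by 2.74 ± 0.20 in the libraries labelled Mga knockout, and Cldn6 fell by 2.22 there and by 3.81 in L3mbtl2 knockout. The median, mean and direction of the primed list differed in sign, at 0.12, 0.07 and down in the libraries labelled Mga knockout, 0.00, -0.42 and down in L3mbtl2 knockout and -0.13, 0.12 and up in Pcgf6 knockout.

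Neuroectoderm genes rose and fell at 3 and 5, 2 and 4, and 0 and 1 of 14 members in the libraries labelled Mga knockout, L3mbtl2 knockout and Pcgf6 knockout (0.254, 0.448 and 0.78), Map2, a neuronal microtubule protein, falling by 2.34 and 1.89 in the first 2. In Pcgf6 knockout that list had a median of 0.02, a mean of 0.05 and a downward test. Mesoderm and primitive streak genes did so at 6 and 2, 4 and 4, and 3 and 2 of 18 (0.125, 0.98 and 0.203), with a median of 0.18, a mean of 0.02 and a downward test in L3mbtl2 knockout. Cdx1 rose in all 3, by 2.41, 2.08 and 2.84. Endothelial and blood genes did so at 0 and 2, 3 and 1, and 0 and 0 of 9 (0.308, 0.753 and 0.942), where limma's smallest unadjusted p in Pcgf6 knockout was that of Tek (-1.62 ± 0.54, adjusted p = 0.0977). Of the MYC, MAX and MXD family 3 and 3, 2 and 2, and 0 and 2 of 13 rose and fell (0.403, 0.753 and 0.645), and Mycn fell in all 3, by 0.83, 1.84 and 1.02. That family had a median of 0.18, a mean of 0.00 and a downward test in L3mbtl2 knockout, and 0.08, -0.02 and a downward test in Pcgf6 knockout. S phase and E2F targets rose and fell at 6 and 6, 4 and 8, and 2 and 0 of 26 (0.645, 0.588 and 0.645), with a median of 0.00 and a mean of -0.10 in L3mbtl2 knockout. E2f2 rose by 1.35, 0.98 and 1.43, and Ccne1, a cyclin of S phase entry, fell by 2.03 in the libraries labelled Mga knockout. Interferon response genes rose and fell at 3 and 3, 1 and 4, and 0 and 1 of 12 (0.856, 0.231 and 0.403), and Bst2 fell by 0.86 and 1.38 in the first 2. Endoplasmic reticulum stress genes did so at 5 and 3, 1 and 6, and 0 and 0 of 17 (0.812, 0.0787 and 0.645), with Trib3 falling by 0.99 and 2.00 in the first 2 and Atf3 at -0.62 ± 0.22 (adjusted p = 0.112) in Pcgf6 knockout.

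Adjusted over the list alone, these counts of risen and fallen members changed to 9 and 10 for other Polycomb subunits, 7 and 7 for S phase genes and 6 and 3 for interferon genes in the libraries labelled Mga knockout. In L3mbtl2 knockout they changed to 7 and 8 for primed epiblast, 3 and 4 for neuroectoderm and 5 and 8 for S phase genes, and in Pcgf6 knockout to 1 and 2 for neuroectoderm, 5 and 2 for mesoderm and 1 and 2 for the MYC family. At the other lists of that group the counts adjusted over the list alone were the same.

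**Figure D3:**
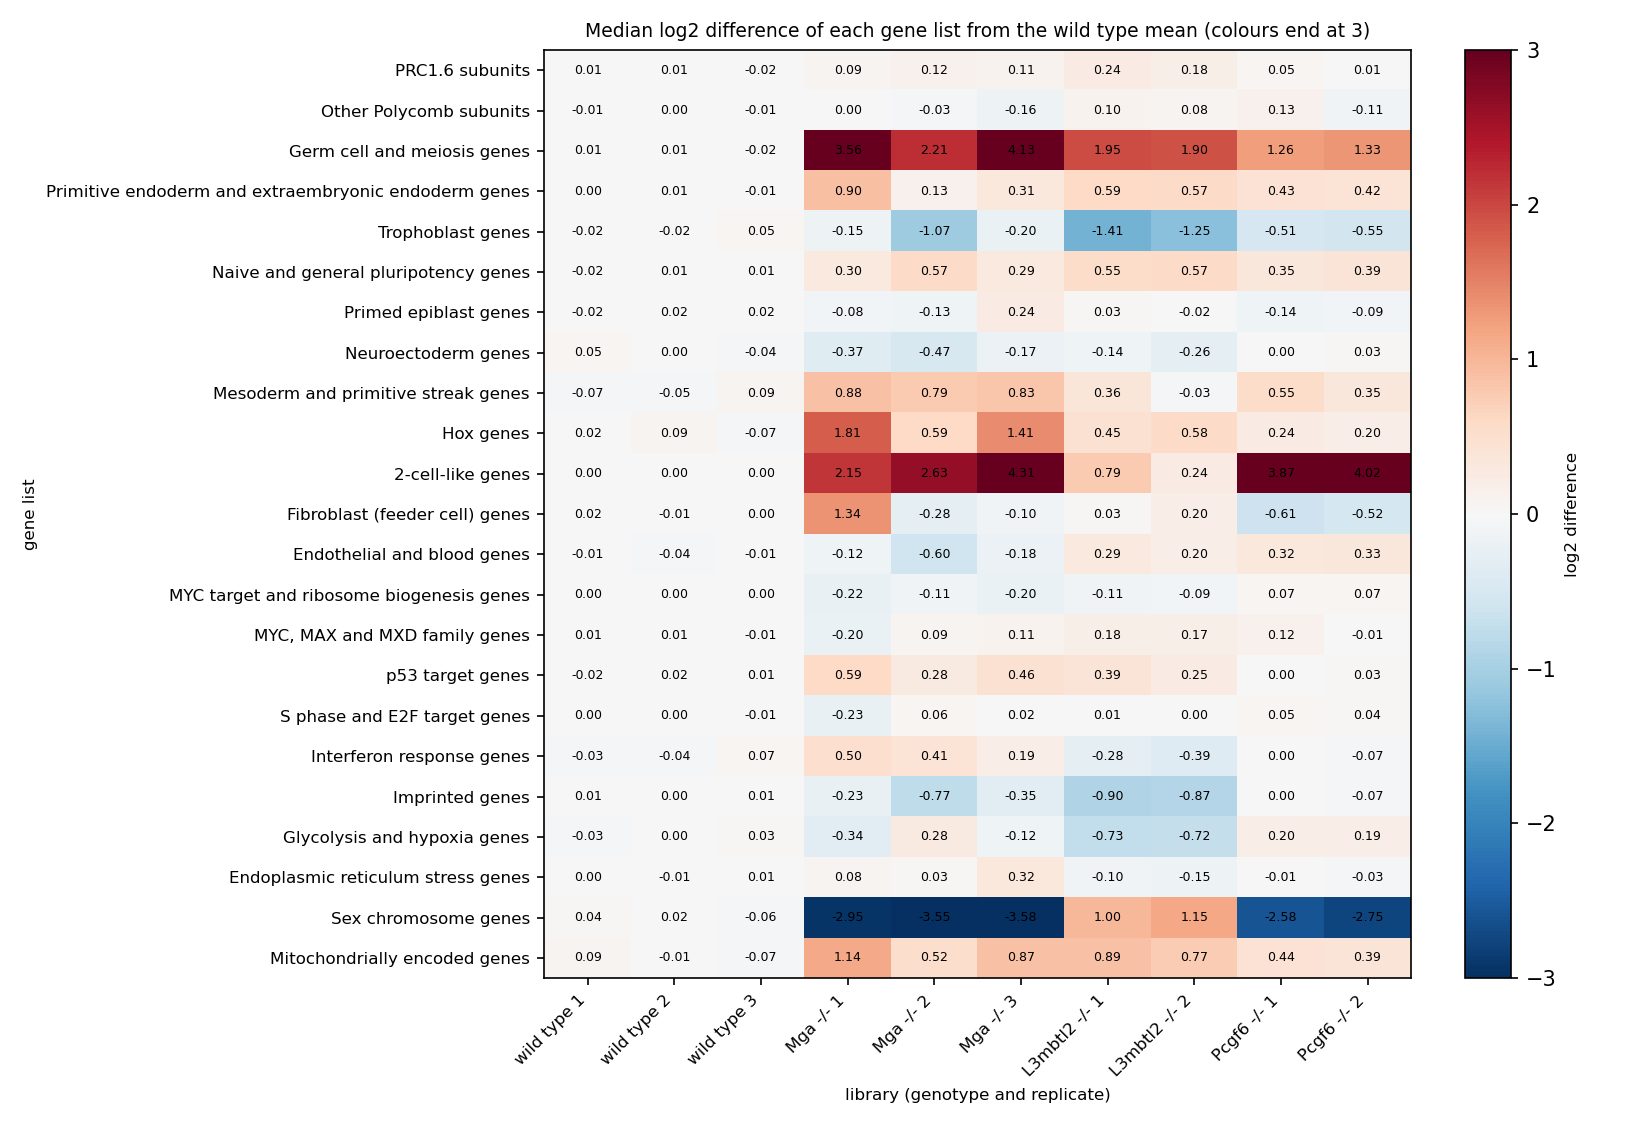
Median log2 difference of each gene list from the wild type mean, for each of the 10 libraries (colour scale ends at 3, numbers give the medians). Germ cell genes are higher in all 7 knockout libraries (1.26 to 4.13), sex chromosome genes are lower in the libraries labelled Mga knockout and in Pcgf6 knockout, and fibroblast genes are higher in the library labelled Mga knockout replicate 1 (1.34).

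Each knockout was also set directly against the others. Tex12 was higher in the libraries labelled Mga knockout than in L3mbtl2 knockout by 8.86 ± 0.39 (SE, adjusted p = 5.17e-06) and than in Pcgf6 knockout by 6.05 ± 0.39 (adjusted p = 4.76e-05). Slc25a31 was higher than in L3mbtl2 knockout by 6.20 ± 0.19 (adjusted p = 1.17e-06). Rnf212, a meiotic recombination factor with 3 reads in L3mbtl2 knockout, had a rate 525-fold higher in the libraries labelled Mga knockout (95% counting interval 179 to 2550). Germ cell genes were higher in the libraries labelled Mga knockout than in L3mbtl2 knockout at 21 of 57 and lower at 2 (median 0.78, adjusted p = 2.23e-06, and adjusted p = 0.598 with an estimated correlation). Against Pcgf6 knockout they were higher at 28 and lower at 1 (median 1.63, adjusted p = 1.24e-12, and adjusted p = 0.52 with an estimated correlation). The 2-cell-like genes were lower in L3mbtl2 knockout than in Pcgf6 knockout at 14 of 15 (median -3.09, adjusted p = 1.44e-06, and adjusted p = 0.598 with an estimated correlation), Zscan4f by 4.43 (SE 0.72, adjusted p = 0.00318). Lyz2 was lower in the libraries labelled Mga knockout than in L3mbtl2 knockout by 8.49 (adjusted p = 0.00163). Eif2s3y was higher in L3mbtl2 knockout than in Pcgf6 knockout by 4.46 ± 0.52 (adjusted p = 0.000853). Between the libraries labelled Mga knockout and L3mbtl2 knockout 3591 genes differed, 1707 higher and 1884 lower. The same comparison with Pcgf6 knockout gave 3550 genes, 1887 and 1663, and L3mbtl2 knockout against Pcgf6 knockout gave 4803 genes, 2616 and 2187. All 3 balances turned under median-of-ratios size factors, to 1756 and 1731, 1697 and 1826, and 2266 and 2462, and the last 2 also under upper-quartile scaling, to 1568 and 2018 and to 2298 and 2439. The 3 counts were 634, 231 and 9809 with only the groups compared in the fit, and 2001, 2301 and 2868 without the shifted chromosomes. There the first turned to 1204 higher and 797 lower (60.2% higher against 47.5%) and the last to 1241 and 1627 (43.3% against 54.5%). With a spread per group the second was 2283 and the last 10429. Without L3mbtl2 knockout replicates 1 and 2 the first of these counts was 1098 and 1188 and the last 1635 and 1775. Without Pcgf6 knockout replicates 1 and 2 the second was 819 and 772 and the last 1807 and 1736. Without the libraries labelled Mga knockout replicates 1 and 2 the first was 5862 and 5665, and without replicate 2 the second was 6983 and the last 7359.

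Calls overlapped between the knockouts. The libraries labelled Mga knockout and L3mbtl2 knockout shared 2012 higher and 1476 lower genes, against 838.2 and 437 for independent lists. In the same pair 232 genes were called in opposite directions. With Pcgf6 knockout, the libraries labelled Mga knockout shared 559 higher and 518 lower genes (independent 195.5 and 121.2), and L3mbtl2 knockout shared 514 and 373 (independent 200.2 and 121.2). Under median-of-ratios size factors the balance of higher and lower turned in all 3 pairs, to 1492 and 1892, 474 and 626, and 418 and 509. Chromosomes 11 and 16 were lower in the libraries labelled Mga knockout (-0.36 and -0.32) and in Pcgf6 knockout (-0.37 and -0.35). That can add genes lower in both. Without the shifted chromosomes fewer genes were tested, and in both pairs with Pcgf6 knockout the shared lower genes fell by a larger share than the higher. Those counts are given for all 3 pairs with the processing choices below. Across genes, log2 fold changes correlated at 0.601, 0.52 and 0.469 in these pairs (simulated 0.45, 0.449 and 0.401), with covariances of 0.640, 0.369 and 0.345 (simulated 0.073, 0.0728 and 0.0726). The share of genes with the same sign was 75%, 67.2% and 63.8%, against 64.8%, 64.7% and 63% simulated. By this measure both pairs with Pcgf6 knockout lay near the simulated value. The draws gave every library a spread pooled over the groups, while wild type varied less (median standard deviation 0.086 against 0.338 in Mga knockout). The simulated values can thus be too high, and lying near them decides nothing. In all 3 knockouts 408 genes were higher (45.7 for independent lists), including Rhox13 and Mael. In all 3 knockouts 328 were lower (20.2 for independent lists), including Krt8, Krt19, Lefty1 and Igf2. Igf2, Krt8 and Krt19 did not pass in Pcgf6 knockout without either Pcgf6 knockout library (adjusted p from 0.0522 to 0.105). Leaving out 1 library moved the genes higher in the first pair to between 973 (without L3mbtl2 knockout replicate 1) and 3148 (without the library labelled Mga knockout replicate 2), and those lower to between 808 and 2248 with the same libraries. For the libraries labelled Mga knockout and Pcgf6 knockout the ranges were 72 to 1446 and 56 to 1064, and for L3mbtl2 and Pcgf6 knockout 77 to 1336 and 37 to 939, lowest without a Pcgf6 knockout library and highest without the library labelled Mga knockout replicate 2. Genes shared by all 3 cannot outnumber those of a pair, so without a Pcgf6 knockout library the 408 would be at most 72 and the 328 at most 37 to 45. Such a fit leaves 1 library in the group and uses a spread shared by all groups, so a call lost there need not be a change lost. Because the 3 wild type libraries could not be split, part of the excess may come from the shared controls.

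Expression also differed between groups by chromosome. Genes of chromosome 11 had a median log2 fold change below that of the other genes by 0.31, 0.47 and 0.48 in the libraries labelled Mga knockout replicates 1, 2 and 3 and by 0.41 in each of the Pcgf6 knockout libraries. Values per library rest only on tested genes with more reads, 844 of 1352 on chromosome 11 and 4 of 10 on Y. Values per comparison rest on all tested genes. As a test per comparison, chromosome 11 lay at -0.36 in the libraries labelled Mga knockout (adjusted p = 6.93e-09) and -0.37 in Pcgf6 knockout (adjusted p = 6.14e-13), where the genes between 88098058 and 102925124 lay at 0.06. Chromosome 16 lay at -0.32 (adjusted p = 2.93e-05) and -0.35 (adjusted p = 8e-12). Chromosome 1 lay at 0.65 in L3mbtl2 knockout (adjusted p = 1.53e-11). In the library labelled Mga knockout replicate 1, genes of chromosomes 1, 6, 12, 14 and 18 lay 0.49, 0.46, 0.45, 0.31 and 0.39 above the others, chromosomes that hold Nanog (6), Gata4 and Nid2 (14) and Lox (18). Chromosome Y lay at -2.62 in the libraries labelled Mga knockout (adjusted p = 0.0144), -2.21 in Pcgf6 knockout (adjusted p = 1.86e-05) and 0.79 in L3mbtl2 knockout (adjusted p = 0.419).

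**Figure D4:**
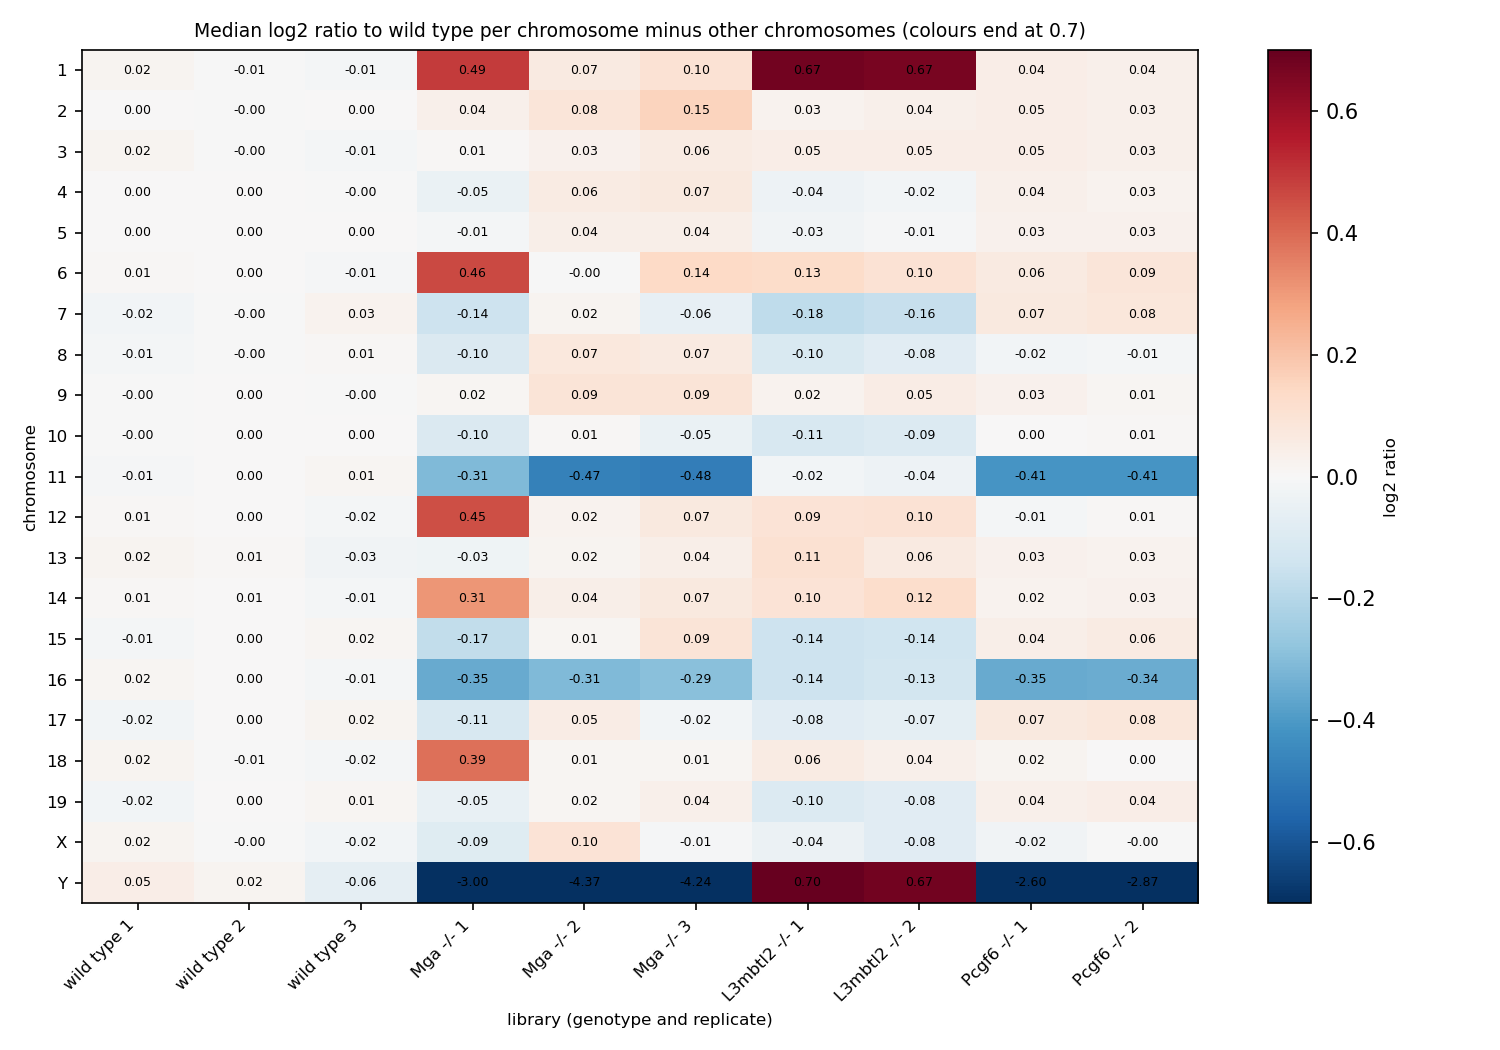
Median log2 ratio to the wild type mean of the genes of each chromosome, minus that of all other chromosomes, for each of the 10 libraries (colour scale ends at 0.7). Only tested genes with more reads are used (844 of 1352 on chromosome 11 and 4 of 10 on Y). Chromosomes 11 and 16 are lower in all libraries labelled Mga knockout and in Pcgf6 knockout, chromosome 1 is higher in L3mbtl2 knockout (0.67 in each library), and 5 chromosomes are higher in the library labelled Mga knockout replicate 1.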

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

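The tests of chromosome segments and of macrophage markers not looked at before were written before their results were seen, and the other tests of this part were chosen only after. The values of the next 3 paragraphs were picked by the limma test of the difference between a pair of knockouts. For the genes, the effects against wild type also went opposite ways. No group had 4 samples, so no test for a single sample far from its group was run.

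Between the libraries labelled Mga knockout and L3mbtl2 knockout 3591 genes differed. List medians of the difference were 0.78 for germ cell, 1.12 for trophoblast, 0.59 for mesoderm, 1.12 for Hox, 2.58 for 2-cell-like, 0.70 for glycolysis, 0.31 for endoplasmic reticulum stress and -3.79 for sex chromosome genes. All of these list calls were lost with an estimated correlation, at adjusted p = 0.52 to 0.675. The differences of macrophage genes were -7.32 at Ccl6 (-5.47 against wild type in the libraries labelled Mga knockout and 1.85 in L3mbtl2 knockout, adjusted p of the difference = 5.08e-05), -7.38 at Pf4 (-4.76 and 2.62), -6.71 at Clec4n (-4.68 and 2.03), -6.36 at C1qa (-4.28 and 2.07) and -2.18 at Spi1 (-1.01 and 1.17). Log2 values understate genes near 0, and in read rates Pf4 (1 read in the libraries labelled Mga knockout) was 1020-fold lower (95% counting interval 182 to 40200) and C1qa (3 reads) 278-fold lower (94.8 to 1350). Y-linked Uba1y and Uty differed by -5.06 (-4.22 and 0.83) and -4.53 (-3.53 and 1), Uba1y with 3 reads and a rate 351-fold lower (120 to 1710). Mid1 differed by 5.16 (1.07 and -4.09), Syce1 by 4.66 (4.31 and -0.35) and Otx2 by 3.98 (2.74 and -1.24). Among stress and metabolic genes the differences were -1.82 at Pmaip1 (-1.03 and 0.79), 1.70 at Ddit4 (0.52 and -1.18), 1.5 at Asns (0.69 and -0.81), 1.29 at P4ha2 (0.32 and -0.97), 0.87 at Sesn2 (0.33 and -0.54) and -0.69 at Hk2 (-0.32 and 0.38). Pcgf2 differed by -0.95 (-0.40 and 0.55) and Eif4a1 by -0.58 (-0.33 and 0.25).

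Between the libraries labelled Mga knockout and Pcgf6 knockout 3550 genes differed. List medians were 1.63 for germ cell, 1.1 for Hox, -0.98 for 2-cell-like, 0.71 for fibroblast, -0.26 for MYC target, 0.46 for p53 target and -0.46 for imprinted genes. All of these list calls were lost with an estimated correlation, at adjusted p = 0.393 to 0.771. Pf4 differed by -5.81 (-4.76 and 1.05), C1qa by -5.53 (-4.28 and 1.24), Pcgf2 by -0.85 (-0.40 and 0.46), Zic2 by 1.40 (0.57 and -0.82), Isg15 by 2.23 (0.97 and -1.26) and Hk2 by -1.03 (-0.32 and 0.71). In read rates Pf4 was 346-fold lower (61.5 to 13700) and C1qa 155-fold lower (52.6 to 759).

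Between L3mbtl2 knockout and Pcgf6 knockout 4803 genes differed, with list medians of -0.47 for trophoblast, -3.09 for 2-cell-like, -1.07 for imprinted, -0.82 for glycolysis and 3.09 for sex chromosome genes. All of these list calls were lost with an estimated correlation, at adjusted p = 0.179 to 0.771. Uba1y differed by 3.6 (0.83 and -2.77), Uty by 3.30 (1 and -2.30), Pcgf6 by 1.78 (0.22, with adjusted p from 0.00116 to 0.296 over the alternatives, and -1.56), Syce1 by -3.91 (-0.35 and 3.57), Otx2 by -2.53 (-1.24 and 1.29), Zic2 by 1.84 (1.01 and -0.82) and Eif4a1 by 0.68 (0.25 and -0.43).

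A first pattern lies in whole chromosomes, lower at 11 and 16 in the libraries labelled Mga knockout and in Pcgf6 knockout and higher at 1 in L3mbtl2 knockout. A change in copy number of whole chromosomes would move all parts alike, and 24 of 25 segments shifted with their chromosome by over 0.1 on the log2 scale. The exception, a run of chromosome 11 from 88098058 to 102925124 in Pcgf6 knockout with a median of 0.06, argues against a change of the whole of that chromosome there. The rise of 5 chromosomes in the library labelled Mga knockout replicate 1 was seen in both other libraries at 0 of the 5 (highest other median 0.141). It was thus not common to the libraries so labelled. The 5 were picked on these same values, and replicate 2 held wild type levels of Mga. For these reasons the test does not decide on an effect of Mga loss. For the fall of Y-linked genes a second X chromosome is argued against by a median of X-linked genes of 0.07. Loss of chromosome Y in most or all cells, and copy number gained or lost in culture, stay open as hypotheses that DNA reads could test.

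A second pattern is in macrophage markers, most of which were lower in the libraries labelled Mga knockout and higher in L3mbtl2 knockout, though they were not tested as a list. RNA from macrophages in the cultures would bring other macrophage transcripts along, and the 22 markers not looked at before had a median of 1.38 in L3mbtl2 knockout, against 1.78 for those looked at, with 21 higher and 13 called. Among those looked at, Lyz2 was at 1.71 in L3mbtl2 knockout, near their median, and both libraries lay above every wild type library. It did not pass in a fit that shares 1 spread with the libraries labelled Mga knockout. Against macrophage RNA, 1 of the 22 was called lower in L3mbtl2 knockout (Coro1a, -2.02), and Arg1 (-0.31) and Cd68 (-0.17) were not higher. Laptm5 was at 0.55 in the libraries labelled Mga knockout. In the libraries labelled Mga knockout replicates 2 and 3, 5 markers kept over 50% of their wild type level. Regulation by the knocked out gene cannot be told apart from RNA of macrophages. Of the markers, 47.4% were over 2-fold higher in replicate 1 than in both other libraries labelled Mga knockout, between the bounds set for either answer.

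The last pattern is the library labelled Mga knockout replicate 2, with Mga at 106% of the wild type mean. A sample of another group under a wrong label is argued against, as 84.2% of 101 genes high in the other libraries labelled Mga knockout were higher there than in every library of the other groups. Wild type cells in the sample are argued against by Y-linked genes at a median of 0.589% of wild type, with Kdm5d, Uty and Ddx3y under 1% and Eif2s3y and Uba1y without reads. Of the 10 genes behind the median, Gm37158, Mid1-ps1 and Gm47283 stood at 200%, 625% and 957%, above the level that wild type cells could bring. Reads from a changed Mga gene that makes no working protein stay open, because values per gene cannot show a change in 1 exon, and reads over single exons would test it. For the count of 6210 genes between these libraries and wild type, 1 of 10 splits of the 6 samples gave as many, the real one, and the highest other gave 0 with limma (up to 1450 at an unadjusted p below 0.05, against 7772). The 10 splits are too few for a share under 0.05.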

How the results depend on the processing

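The tests with a pseudocount of 1 or 0.01, with a spread per group and without the shifted chromosomes were chosen only after the data were seen. No called direction of a named gene turned under any alternative run. Of 313 named results tested under median-of-ratios size factors 307 kept their side of the threshold, and under limma-voom 300 of 314 did, with 13 no longer past it and 1 newly past it. When 1 library was left out, 265 to 310 kept their side. The planned count-based test, the quasi-likelihood F test of edgeR, was not run, and limma-voom was the only test run on the recovered reads. A group left with 1 library was assumed to vary like the others. At a depth of 19.4 to 26.7 (1e6 reads), genes near 0.5 FPKM rest on few reads.

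In this paragraph, pairs are given in the order Mga and Pcgf6, then L3mbtl2 and Pcgf6, each with genes higher in both and then lower in both. With a spread per group the counts against wild type were 3709, 11110 and 7503 for Mga, L3mbtl2 and Pcgf6 knockout, 2283 for Mga against Pcgf6 and 10429 for L3mbtl2 against Pcgf6. Pairs were at 1208, 1073, 2530 and 1842. With only the groups compared they were 4054, 10525 and 7096, and between knockouts 634 (Mga and L3mbtl2), 231 (Mga and Pcgf6) and 9809 (L3mbtl2 and Pcgf6), with pairs at 1113, 1084, 2108 and 1920. Mga libraries had a spread of 0.338 against 0.064 and 0.067 in the other knockouts, and both settings stop sharing it. The replicate numbers did not pair the samples (13 pairs, correlations from -0.02 to 0.035), so a block of replicate numbers was only a check. A replicate block gave 992 for Pcgf6, 328 lower in Mga and Pcgf6, and 333 and 229 for the last pair, for which the cause was not tested. It also ended the list call of glycolysis genes in Pcgf6 knockout (adjusted p = 0.0704). Without 4958 genes of the shifted chromosomes, fewer genes were tested. The counts were 4067, 4045 and 782 against wild type, 2001, 2301 and 2868 between knockouts, 1320 higher and 975 lower in Mga and L3mbtl2, and pairs at 355, 176, 318 and 162. There the sex chromosome list turned in the libraries labelled Mga knockout (adjusted p = 0.549), being left with Xist and Tsix. With an estimated correlation camera called 0 list tests, against 23 of 69 with the preset one. With fry, germ cell genes passed in Mga, L3mbtl2 and Pcgf6 knockout (adjusted p = 5.08e-05, 0.0012 and 0.00415). Fibroblast, glycolysis, trophoblast and mitochondrially encoded genes in Pcgf6 knockout, all called by camera, did not pass fry (adjusted p = 0.34, 0.225, 0.0638 and 0.0659).

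With 1 library left out, the counts ranged from 4198 to 8647 for Mga against wild type, 2829 to 8515 for L3mbtl2, 154 to 3975 for Pcgf6, 1098 to 5862 for Mga against L3mbtl2, 772 to 6983 for Mga against Pcgf6 and 1635 to 7359 for L3mbtl2 against Pcgf6. Genes higher and lower in both ranged from 973 to 3148 and 808 to 2248 for Mga and L3mbtl2, 72 to 1446 and 56 to 1064 for Mga and Pcgf6, and 77 to 1336 and 37 to 939 for L3mbtl2 and Pcgf6. The lowest counts left a group with fewer samples, and the highest of most left out the library labelled Mga knockout replicate 2. List tests called ranged from 22 to 25.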

Other observations

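The test of X-linked genes in this part was chosen only after the result was seen. Of the 408 genes higher in all 3 knockouts 33 lay on chromosome X (8.1%, against 3.8% of the 15731 tested). The hypothesis that X-linked genes are more often among them gave an odds ratio of 2.30 (Fisher's exact test, p = 5.55e-05). Without the Xlr, Rhox, Mage and Usp families, whose copies can share reads, 21 of 396 were left, with an odds ratio of 1.54 (Fisher's exact test, p = 0.072), so the test left it open. Without a Pcgf6 knockout library at most 72 of the 408 could be shared, and the test was not repeated there.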
